A study of Homo sapiens with 32 samples.

How the data were processed

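The series holds 32 human RNA-seq libraries, from 4 cell lines, 2 labelled genotypes and 2 treatments with 2 libraries in each of 16 groups, and each library was assigned to its group by its title. Per the labels' protocols, cells were grown in DMEM with serum, treated for 6 h with DMSO or with OTS964 at 100 nM, and RNA was taken with a column kit and made into libraries with a SMARTer mRNA kit. The characteristics in the labels are filed under tags that do not match their contents, so titles and the design text were used.

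The authors deposited 1 table of transcripts per library, with transcript length, effective length, TPM and estimated counts for 87398 transcript identifiers, per the file headers. The estimated counts in the deposited files are not whole numbers and are not normalized. The TPM values in the deposited files are normalized by the authors to transcript length and library total. The tool that made them is not given in the sources used here, although the columns have the layout of a lightweight quantification tool. The submitters' processing notes name only the mouse builds GRCm38 and mm10, while the transcript identifiers are those of human RefSeq and matched human genes, so no coordinates are printed. Such tools assign each read among transcripts by an estimate, so a transcript or gene listed at 0 can share sequence with others that took its reads, and CDK11A and CDK11B, the histone genes and other close paralogs share reads.

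Transcripts were matched to gene symbols by versionless identifiers through a human RefSeq gene table and a transcript table of GENCODE, which together matched 42575 of the 87398 identifiers (48.7%). Of the curated coding identifiers 36260 of 36585 matched (99.1%), of the predicted coding ones 6315 of 31064 (20.3%), and of 19749 numbered identifiers without a gene name none. Matched transcripts held 87.55% of the reads on average. The other 12.45% of the reads, 9.08% of them all on predicted transcripts, were not used here and stayed out of the library sizes and tests. The share of reads on predicted transcripts, most of them unmatched, differed with treatment in wild-type cells. It lay between 8.97% and 9.46% in wild-type OTS964 libraries and between 11.38% and 12.47% in wild-type DMSO libraries. In G579S OTS964 libraries it lay between 10.82% and 12.36%. Counts were summed to 18844 genes and rounded to whole numbers. A library had between 16091376 and 29742687 estimated reads over all transcripts. Its 10 most abundant genes held between 4.93% and 9.30% of the reads assigned to genes. At the smallest size, 14327673 matched counts, a gene at 0 has an upper limit of 3 counts. Intervals and floors of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

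Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersion, TMM scaling and edgeR's filter on low counts by group, which left 14314 genes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts within a line came from 1 fit of 16 groups over all 32 libraries, with 16 residual degrees of freedom. The contrasts across lines came from additive fits with the line as a block. The comparisons were the response to OTS964 in wild-type and in G579S cells, the difference of these responses, the genotypes under DMSO, and the response of each wild-type line minus the mean of the others. TMM factors averaged 0.768 ± 0.051 in the 8 wild-type OTS964 libraries and 1.121 ± 0.026, 1.124 ± 0.036 and 1.037 ± 0.063 (SD, n = 8) in the wild-type DMSO, G579S DMSO and G579S OTS964 libraries. CPM values in the text are scaled by these factors. A fold change against a group whose libraries were all at 0 is given as a lower bound from a floor of 3 counts per library. Transcript usage was tested with edgeR's diffSpliceDGE function and the Simes method in genes with several matched transcripts.

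Gene lists fixed before the data were examined were tested with camera of limma 3.58.1, with its preset correlation of 0.01, and again with the correlation estimated from the data and with fry. The p-values were adjusted over the lists of a contrast. The lists were replication-dependent histones, histone mRNA processing, DNA replication and E2F targets, homologous recombination and Fanconi, mitosis, spliceosome core, SR proteins and splicing kinases, the CDK11 complex and other transcription kinases, cleavage and polyadenylation, immediate early genes, ATF4 and the unfolded protein response, heat shock, interferon-stimulated genes, NF-kB and cytokines, cholesterol synthesis, apoptosis regulators, cytosolic ribosomal proteins, nuclear oxidative phosphorylation, KRAB zinc fingers, and markers of melanocytes, colorectal, breast epithelial and mesenchymal cells. Lists of mitochondrially encoded genes and of nuclear noncoding RNAs could not be tested, since 0 of 15 and 1 of 22 members matched an identifier. Planned tests of transcripts annotated with a retained intron, by share and by usage, were not run, because the matched identifiers carry no such annotation. Intron retention was not analysed here. Exon numbers and genomic spans came from the GENCODE annotation of release 29, for 14281 of 14314 genes (99.8%).

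Samples, comparisons, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined, and additions are described as chosen after the data were seen. By that rule the text names, of genes at 5 CPM or more, the 12 largest changes each way across wild-type lines that passed in the same direction in each line, the 5 largest each way across lines in the other contrasts and fewer per line, up to 4 members of each list with the smallest adjusted p, the largest changes in transcript usage, and CDK11A, CDK11B, CCNL1, CCNL2, SF3B1, SRSF1, MYC, CDKN1A and MDM2 always; the text gives a part of these for single lines. Among the marker genes of identity, CDX2 lies outside this rule and was named after its value was seen. Y-linked genes were left out, and some genes that met the rule, 1 gene list and 1 planned comparison of lines are not reported here.

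The gene tests of 3 contrasts and the test of transcript usage were first tested on simulated counts drawn from the means and library sizes of the real samples with 200 changed genes. The simulation used 1 assumed dispersion for all genes and libraries, whereas real replicate pairs differed in their noise. Its rates need not hold for the real data. The list tests and the other contrasts were not simulated. For the wild-type response in A375 (13975 genes), 87% of 2-fold and 98% of 4-fold changes were recovered and 5.1% of calls were false. For the wild-type response across lines (13982 genes) both sizes were recovered at 100%, with 6.5% false calls, and for the difference of responses at 99% and 100%, with 4.3% false calls. For transcript usage in wild-type cells (6111 genes), 97.5% of 4-fold changes were recovered, with 4.4% false calls. Alternatives tried were DESeq2 1.42.0 by its Wald test, DESeq2's size factors with edgeR's test, library totals alone, no filter and a stricter filter on low counts, length-scaled TPM, a minimum fold change of 2, a fit of the 8 libraries of a line alone, the replicate number as a block, the mean of the contrasts within lines, each line left out, each library left out, and fits without libraries that stood apart. Relabelled samples were drawn 100 times per contrast, and whole groups were exchanged within lines in all 8 ways for 3 contrasts.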

Results

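RNA was sequenced from 4 established human cancer cell lines: A375 from melanoma, Cal51 and MDA-MB-231 from breast cancer, and DLD1 from colorectal cancer. Each line was grown as cells labelled wild-type and as cells labelled G579S. The design text calls the former sensitive to inhibition of CDK11 and the latter resistant. As background, CDK11A and CDK11B encode near-identical cyclin-dependent kinases that act with the cyclins CCNL1 and CCNL2 in transcription and splicing. OTS964 is a small-molecule inhibitor of CDK11. Cells received OTS964 at 100 nM or the solvent DMSO for 6 h, with 2 libraries in each of the 16 groups and 32 libraries in all. A library held between 16091376 and 29742687 estimated reads over all listed transcripts. The labels do not say that the 2 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. No library was identical to another, and replicate counts differed by more than sampling noise in every group.

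CDK11B stood at 639 ± 47.7 CPM (SD, n = 2) in the DMSO libraries labelled MDA-MB-231 G579S and at 59.1 ± 3.87 CPM (SD, n = 2) in the wild-type ones, a log2 difference of 3.43 ± 0.17 (SE) with an adjusted p of 2e-10. With OTS964 the corresponding levels were 865 ± 21.1 and 65.7 ± 7.91 CPM. The other groups lay between 32.5 and 53.9 CPM. CDK11A and CDK11B share most of their sequence, so the split between them is uncertain. Their sum showed the same contrast, with 664 ± 53.4 CPM in MDA-MB-231 G579S and 92.2 ± 2.81 CPM in MDA-MB-231 wild-type under DMSO. In Cal51 the DMSO difference in CDK11B was -0.54 (adjusted p = 0.027), from 39.5 and 25.5 CPM in the G579S libraries and 46.3 and 48.2 CPM in the wild-type ones. It was -0.26 without the second G579S library and -0.89 without the first, and passed only in the latter case. In A375 the DMSO difference in CDK11A was 0.49 (adjusted p = 0.041).

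The libraries labelled DLD1 wild-type carried the markers of a colorectal line only at a low level. SOX10, a transcription factor of the melanocyte lineage, stood at 716 ± 29.8 CPM (SD, n = 2) in the DMSO libraries labelled DLD1 wild-type, at 592 ± 12.6 CPM in A375 wild-type and at 1.29 ± 0.491 CPM in DLD1 G579S. VIM, which encodes the mesenchymal filament protein vimentin, stood at 3530 CPM in the libraries labelled DLD1 wild-type and at 8.06 CPM in DLD1 G579S. The epithelial adhesion gene CDH1 was at 16.2 against 551 CPM, EPCAM at 21.8 against 689 CPM and the intestinal transcription factor CDX2 at 3.25 against 96.3 CPM. In mean log2 CPM, the melanocyte markers averaged 4.02 ± 0.10 in the libraries labelled DLD1 wild-type and -0.84 ± 0.04 in DLD1 G579S. The colorectal epithelial markers averaged 2.16 ± 0.38 and 6.48 ± 0.01, against -1.40 in A375 wild-type. These 4 libraries are therefore named by their labels throughout, and every contrast that uses them rests on a label that the markers went against. The across-line counts were also computed without them.

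**Figure D1:**
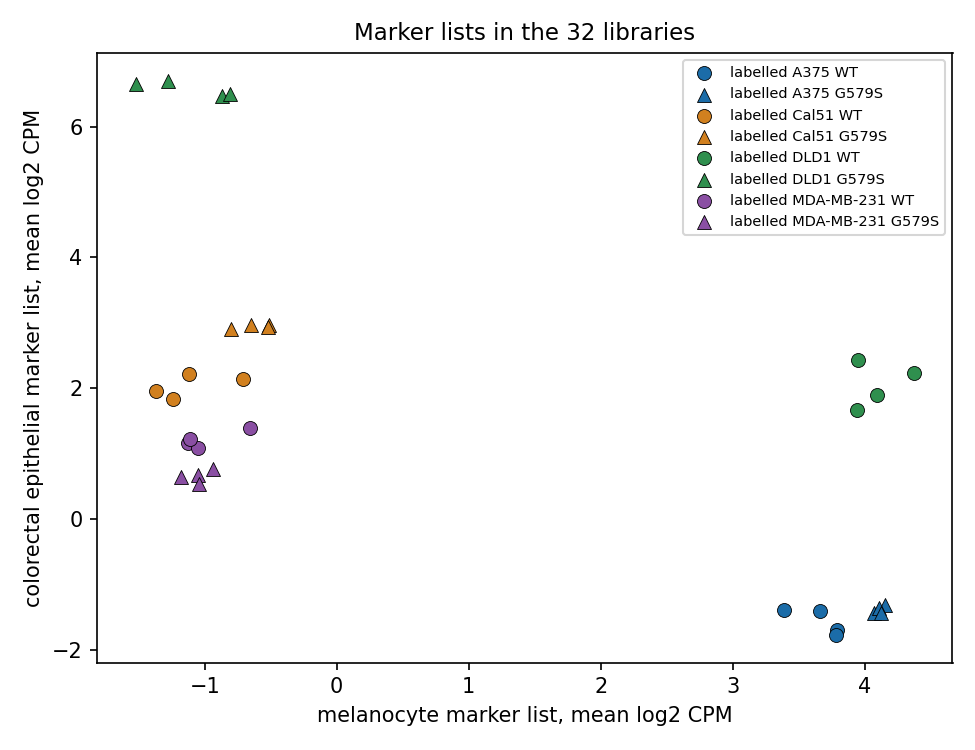
Each point is 1 of the 32 libraries, placed by the mean log2 CPM of the melanocyte markers on the x axis and of the colorectal epithelial markers on the y axis, with colour for the labelled line and shape for the labelled genotype. The libraries labelled DLD1 wild-type lie at the melanocyte level of A375, far from those labelled DLD1 G579S, whose colorectal markers average 6.48 under DMSO.

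In cells labelled wild-type, OTS964 changed a large part of the transcriptome within 6 h. This comparison asks what inhibition of CDK11 does to expression in sensitive cells. CREBZF, a basic leucine zipper transcription factor, rose from 11.8 ± 5.91 to 237 ± 145 CPM (SD, n = 8 libraries each) and CCN1, a secreted matrix protein induced by growth signals, from 453 ± 391 to 5710 ± 1470 CPM. MYC, the growth-promoting transcription factor, rose from 69.4 ± 37.7 to 513 ± 79.5 CPM, and the AP-1 subunit FOSB from 3 ± 2.73 to 35.2 ± 16.4 CPM. N4BP1, a regulator of NF-kB signalling, fell from 34 ± 3.73 to 0.718 CPM, and NDEL1, a dynein regulator, from 42.3 to 1.07 CPM. Across lines, 8424 of the 14314 genes tested passed an adjusted p of 0.05, 3878 higher and 4546 lower. With a fold change of at least 2 as well, the count was 4650, of which 1410 were higher. The count was 7530 without the 4 libraries labelled DLD1 wild-type and 8752 without the first MDA-MB-231 wild-type OTS964 library, which stood apart from its replicate. Both fits were chosen after the data were seen. Relative to the main scaling, scaling by library totals alone moved the median of all genes by -0.55 on the log2 scale and left 21.9% of the called genes higher in place of 46.0%. Directions are therefore relative to the main scaling. Both scalings are relative to the reads of a library, so neither shows whether RNA per cell rose or fell.

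The log2 fold changes across lines were 4.21 ± 0.53 (SE; adjusted p = 7.1e-06) for CREBZF, 4.09 ± 0.30 (adjusted p = 3.4e-08) for CCN1, 3.89 ± 0.68 (adjusted p = 0.00016) for FOSB and 3.08 ± 0.24 (adjusted p = 5.5e-08) for MYC. EDN1, which encodes the vasoconstrictor endothelin, rose by 3.66, the transcriptional repressor PRDM1 by 3.01 and the AP-1 related factor CSRNP1 by 2.90. FAM120AOS, MSANTD4, ZNF460, SNX22 and EID2B completed the 12 highest, at 3.68, 3.43, 3.23, 2.97 and 2.96. PRR14L, a gene linked to cell division, and ZSCAN29, a zinc finger gene, had no count in any of the 8 OTS964 libraries against 22.6 ± 5.88 and 21.2 ± 3.41 CPM under DMSO, at least 99.3-fold and 92.9-fold lower by a floor of 3 counts. KLHL25 and KCTD21, adaptors of ubiquitin ligases, fell, with log2 changes of -8.07 and -8.05, and RBM12B, SRGAP1 and CCDC18 fell, with log2 changes of -6.59, -6.30 and -6.03. GLI2, a Hedgehog transcription factor, NDEL1, N4BP1, ZNF823 and the ubiquitin ligase TRIM35 fell as well, with log2 changes of -5.76, -5.76, -5.83, -5.58 and -5.46. The estimated counts were summed over matched transcripts only, so reads assigned to an unmatched transcript of such a gene would leave its sum. Between 35 and 150 genes per replicate pair were at 0 in one library and at 5 CPM or more in the other. All of the genes named here were past the threshold in the same direction in each of the 4 labelled lines, as their rule of choice required. In all, 1944 higher and 1900 lower genes met this, while 182 genes passed in all 4 with mixed direction. The libraries labelled DLD1 wild-type resembled A375, so agreement in 4 labelled lines is not agreement in 4 distinct ones.

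The lists of ribosomal proteins and of oxidative phosphorylation held almost only genes that rose. All 76 cytosolic ribosomal protein genes rose, by a median log2 fold change of 1.15, for example RPS4X from 931 to 2090 CPM, RPL23A by 1.08, RPS15A by 1.10 and RPS6 by 1.19. The camera test set the list apart from other genes (adjusted p = 8.1e-36), with an adjusted p = 0.1 with an estimated correlation. Of the 49 nuclear genes of oxidative phosphorylation, 47 rose and 0 fell, including the cytochrome oxidase genes COX7C and COX7A2 (1.19 and 1.23) and the ATP synthase genes ATP5F1B and ATP5PD (1.06 and 1.08). Here the camera adjusted p was 3.2e-21, and again adjusted p = 0.1 with an estimated correlation. The counts adjusted over the list alone were the same, 76 and 47. With library totals as the scaling, 75 ribosomal and 40 oxidative phosphorylation genes rose, with medians of 0.60 and 0.50. Under either scaling these are rises relative to other genes, and a change per cell was not measured. Of 38 replication-dependent histone genes 14 rose and 0 fell (12 and 0 adjusted over the list alone). Among them were H2BC21 at 2.17, H1-2 at 1.33, H2BC12 at 1.24 and H2BC5 at 1.05 (camera adjusted p = 0.0032, and adjusted p = 0.1 with an estimated correlation). With library totals 7 of the histone genes rose and 0 fell, and their median was 0.57 in place of 1.1. Of the 10 genes that process histone mRNA, 7 fell and 1 rose (7 and 2 adjusted over the list alone). SLBP, the histone stem-loop binding protein, fell from 141 to 27.5 CPM, and CASP8AP2 and NPAT fell, with log2 changes of -2.17 and -1.62. The list was not set apart (camera adjusted p = 0.13, and adjusted p = 0.22 with an estimated correlation). The scaffold SYMPK stood at 0.55, a sign that is lost at 0.00 with library totals.

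In the list of immediate early genes, the transcription factors and phosphatases induced by growth stimuli, more genes rose than fell. Of 35 tested, 24 rose and 5 fell (25 and 5 adjusted over the list alone), with a median of 1.20. DUSP5, a phosphatase of the ERK kinases, went from 63.9 to 290 CPM while ZFP36L1, an RNA decay factor, rose by 1.20. The camera adjusted p was 0.00034, and adjusted p = 0.22 with an estimated correlation. Of 24 genes of NF-kB and cytokine signalling, 9 rose and 6 fell. TNFAIP3, CXCL8, IL6 and NFKBIA rose by 2.23, 2.23, 2.79 and 1.63 (adjusted p = 0.3, and adjusted p = 0.62 with an estimated correlation). Mesenchymal markers showed 13 of 23 higher and 0 lower, with MSN at 0.97, VIM at 0.79, COL6A1 at 1.30 and CAV1 at 0.86 (adjusted p = 0.0029, and adjusted p = 0.1 with an estimated correlation). With library totals, 4 of the mesenchymal genes fell and 11 rose, and 22 immediate early genes rose and 8 fell.

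In the lists of mitosis and of homologous recombination more genes fell than rose. Of 44 mitosis genes 30 fell and 1 rose, with a median of -0.69. CDCA8, a subunit of the chromosomal passenger complex, fell from 122 to 25.7 CPM, and the mitotic kinase TTK, the centromeric histone CENPA and the spindle motor KIF11 fell, with log2 changes of -2.31, -1.98 and -1.65. The camera adjusted p was 2.8e-05, and adjusted p = 0.45 with an estimated correlation. Of 34 genes of homologous recombination and the Fanconi pathway 21 fell and 2 rose (22 and 2 adjusted over the list alone). BRIP1, BRCA2, FANCB and FANCE fell, with log2 changes of -2.15, -1.71, -1.79 and -2.17 (adjusted p = 0.00073, and adjusted p = 0.17 with an estimated correlation). DNA replication genes and E2F targets split into 17 higher and 25 lower of 51, with CCNE2, E2F7, ORC6 and MCM10 lower at -2.40, -2.69, -2.24 and -1.56. The list did not stand apart (adjusted p = 0.091, and adjusted p = 0.63 with an estimated correlation), but it did with library totals (adjusted p = 0.0033) and without the 4 libraries labelled DLD1 wild-type (adjusted p = 0.039). With library totals the mitosis median was -1.24 and that of homologous recombination -1.49.

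Splicing genes were tested as separate lists, and the lists were not compared with each other. Of 45 genes of the spliceosome core 32 rose and 7 fell (32 and 8 adjusted over the list alone), with a median of 0.41 that turned to -0.14, with 12 genes higher and 21 lower, under library totals. SNRPC, a protein of the U1 particle, rose from 120 to 264 CPM, the Sm proteins SNRPE and SNRPG by 1.09 and 1.00, and SF3B5 by 1.45. The list passed the camera test both with the preset correlation (adjusted p = 2.6e-05) and with the estimated one (adjusted p = 0.032). SF3B1, the branch-site binding protein, rose by 0.64 ± 0.07 (SE; adjusted p = 9.4e-07), and the splicing regulator SRSF1 stood at 0.17 ± 0.06 (adjusted p = 0.027), which became -0.38 with library totals. Of 30 SR proteins and splicing kinases 16 fell and 6 rose. The kinases CLK1, SRPK2 and CLK3 fell, with log2 changes of -2.23, -2.02 and -1.47 and SRSF9 rose by 0.85 (camera adjusted p = 0.17, and adjusted p = 0.45 with an estimated correlation). Among 19 genes of the CDK11 complex and the other transcription-related kinases and cyclins, 10 fell and 2 rose. CDK7, CCNK, CDK13 and SAP30BP stood at -1.56, -1.28, -1.11 and -1.26 (adjusted p = 0.027, and adjusted p = 0.1 with an estimated correlation). CCNL1, a cyclin partner of CDK11, rose from 8.61 ± 4.02 to 54.7 ± 35.4 CPM, by 2.48 ± 0.42 (SE; adjusted p = 0.00013). CCNL2 stood at -0.08 ± 0.20 (adjusted p = 0.75) and, computed from TPM scaled by transcript length, at 0.69. CDK11A fell by 0.36 ± 0.09 (adjusted p = 0.0029) and CDK11B stood at -0.17 ± 0.10 (adjusted p = 0.15). Of 20 cleavage and polyadenylation genes 6 rose and 7 fell. CPSF7 fell from 133 to 31.1 CPM, and CPSF4, PAPOLG and PCF11 stood at -2.87, -2.66 and -1.53 (adjusted p = 0.5, and adjusted p = 0.62 with an estimated correlation).

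CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.81 ± 0.12 (SE; adjusted p = 5.4e-05), whereas MDM2, a ubiquitin ligase, fell from 122 to 61.5 CPM, by 1.13 ± 0.17 (adjusted p = 3.7e-05). The remaining lists moved in both directions or did not stand apart by the camera test. Of 28 genes of ATF4 and the unfolded protein response 14 rose and 7 fell, with the chaperones PDIA4, CALR and HSP90B1 at 1.18, 1.11 and 1.10. The median of 0.27 became -0.27 with library totals, and the mean was 0.00 (adjusted p = 0.17, and adjusted p = 0.51 with an estimated correlation). Of 21 heat shock genes 9 rose and 8 fell (9 and 9 adjusted over the list alone), with HSP90AB1, CACYBP, HSPE1 and HSPD1 at 0.92, 0.87, 0.93 and 0.89. The test gave the direction as up and the median was 0.04, while the mean was -0.14 and the median with library totals -0.51 (adjusted p = 0.32, and adjusted p = 0.45 with an estimated correlation). Interferon-stimulated genes counted 6 higher and 6 lower of 28, with IRF1 and IRF9 lower at -2.37 and -1.81 and ISG15 and OAS3 rising by 0.94 and 0.75. The median of 0.15 stood against a mean of -0.29 and a median of -0.40 with library totals (adjusted p = 0.63, and adjusted p = 0.73 with an estimated correlation). Cholesterol synthesis genes counted 7 higher and 6 lower of 24, with FDPS at 0.87. The camera test gave the direction as up although median and mean were -0.08 and -0.18 (adjusted p = 0.91, and adjusted p = 0.96 with an estimated correlation). Of 27 apoptosis regulators 15 fell and 4 rose (16 and 4 adjusted over the list alone). BAK1 fell from 59.2 to 8.57 CPM, BCL2L2 and BIRC2 stood at -1.55 and -1.13, and BAX rose by 0.87 (adjusted p = 0.065, and adjusted p = 0.21 with an estimated correlation). Of 48 KRAB zinc finger genes 21 fell and 4 rose (19 and 4 adjusted over the list alone). ZNF260, ZNF274, ZNF45 and ZNF37A fell, with log2 changes of -2.01, -1.79, -1.70 and -1.65 (adjusted p = 0.065, and adjusted p = 0.63 with an estimated correlation).

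Among lineage markers, which also report on other cell types in a library, 8 of 19 colorectal epithelial genes rose and 4 fell. KRT8, CDH1 and EPCAM stood at 1.14, 1.02 and 1.01 and MYB fell by 3.72, and the mean of -0.09 differed in sign from the median of 0.68 (adjusted p = 0.34, and adjusted p = 0.65 with an estimated correlation). The melanocyte list counted 2 higher and 2 lower of 14, with S100A1 and MIA at 1.23 and 1.14 and SOX10 and ERBB3 lower at -1.33 and -0.55 (adjusted p = 0.63). Its median of 0.15 became -0.33 with library totals. The breast epithelial list counted 4 higher and 4 lower of 15, with TFF3 at 1.56, ERBB2 at 0.48, EGFR at -1.09 and XBP1 at -0.74 (adjusted p = 0.73), and ERBB2 stood at -0.07 with library totals. Of the 9 lists past the preset camera test, 1, the spliceosome core, passed with the estimated correlation, while 7 lists had an unadjusted p under 0.05 there.

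Line by line, 6561 genes passed in A375 (2980 higher), 7555 in Cal51 (3574 higher), 7154 in the libraries labelled DLD1 (3185 higher) and 6656 in MDA-MB-231 (3449 higher). MYC rose by 3.77 in A375, from 34.5 to 470 CPM, by 2.72 in Cal51, by 3.80 in the libraries labelled DLD1 wild-type and by 2.03 in MDA-MB-231. CCNL1 rose by 2.73, 2.96 and 3.74 in A375, Cal51 and the libraries labelled DLD1, and stood at 0.25 (adjusted p = 0.62) in MDA-MB-231. CDKN1A rose by 0.95, 1.15 and 0.93 in the same order and stood at 0.20 (adjusted p = 0.25) in MDA-MB-231, where CCNL2 fell by 1.12 (adjusted p = 0.0017). In A375, Cal51, the libraries labelled DLD1 and MDA-MB-231, MDM2 fell, with log2 changes of -0.78, -0.92, -0.97 and -1.88 and SF3B1 rose by 0.81, 0.75, 0.63 and 0.39, the last value becoming -0.11 with library totals. Across genes, which are not independent replicates, Spearman's rho between the fold changes of the lines lay between 0.51 and 0.76. Of the 5867 genes past the threshold in both A375 and the libraries labelled DLD1, which resembled A375, 5859 moved the same way. The shares were lower with MDA-MB-231, at 4291 of 4641 genes shared with A375, 4855 of 5200 with Cal51 and 4666 of 4951 with the libraries labelled DLD1. They were 5354 of 5472 for A375 and Cal51 and 5731 of 5847 for Cal51 and the libraries labelled DLD1.

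**Figure D2:**
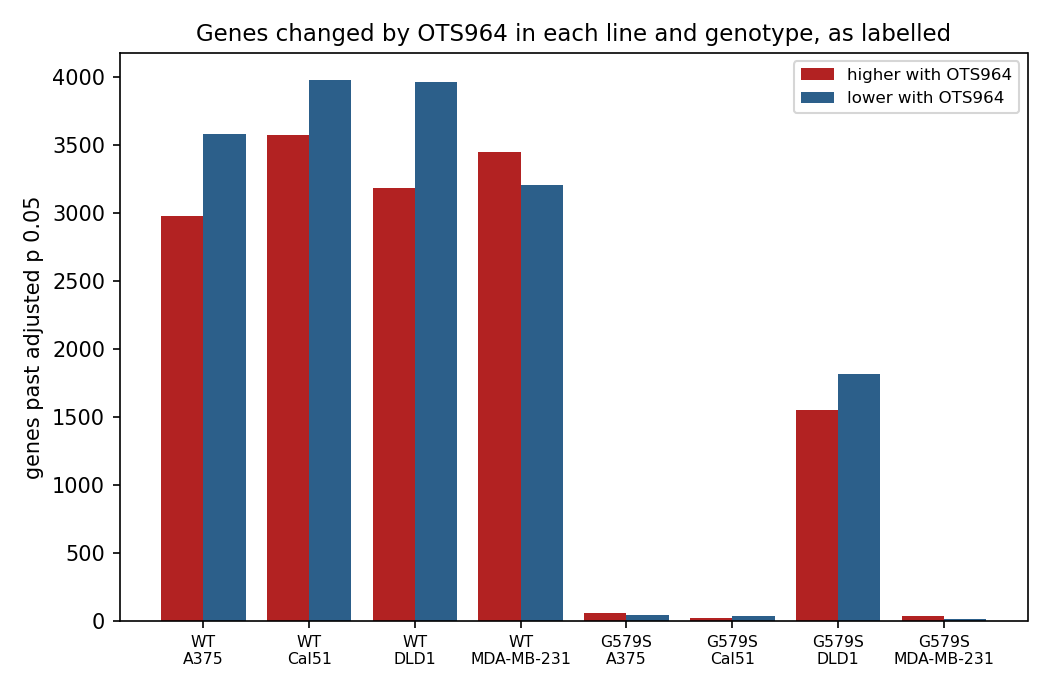
Bars give the number of genes past an adjusted p of 0.05 with OTS964 against DMSO in each labelled line and genotype (n = 2 libraries per group), higher in red and lower in blue. The 4 wild-type contrasts lie between 6561 and 7555 genes, DLD1 G579S at 3369 and the other G579S contrasts between 44 and 94; with library totals as the scaling fewer of the called genes are higher.

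The title of the series names intron retention, which was not analysed here. Gene structure and transcript choice were compared instead. The 319 tested genes with 1 exon had a median log2 fold change of 0.81 across lines in cells labelled wild-type, with 45.8% called higher and 7.5% lower. Genes with several exons had medians of 0.04, -0.19 and -0.30 in the groups with the fewest, middle and most exons, and of 0.24, -0.20 and -0.45 in the groups with the shortest, middle and longest genomic span, whose median spans were 9.3, 33.5 and 119 kb. Across 14281 genes, which are not independent replicates, Spearman's rho of the fold change was -0.13 with exon number and -0.23 with span. Among genes with a mean of at least 5 CPM these were -0.21 and -0.28, and the 166 genes with 1 exon had a median of 1.14, with 68.7% called higher, and of 0.41 in MDA-MB-231. Without the histone list, a choice made after the data were seen, 289 genes with 1 exon had a median of 0.73, 135 rising and 24 falling. Of 10000 random lists of genes with several exons matched on mean expression 0 reached this value, most of their medians lying between -0.40 and -0.01. The lists were not matched on genomic span. In G579S cells the 289 genes had a median of 0.09, and 0 of 10000 such lists reached it either, with most medians between -0.10 and 0.00. Single-exon medians were 0.79 in A375, 0.87 in Cal51, 1.07 in the libraries labelled DLD1 and 0.18 in MDA-MB-231, against 0.11 across lines in G579S cells, where rho was -0.03 with exon number and -0.01 with span. In cells labelled wild-type, rho with exon number was -0.13 in A375, -0.14 in Cal51, -0.14 in the libraries labelled DLD1 and -0.04 in MDA-MB-231. There the groups with the fewest, middle and most exons all had a median of 0, while rho with span was -0.21. Genes with 1 exon, at 0.18, lay below those of several exons and the shortest span, at 0.28. The lines labelled G579S were not alike either. The values of Spearman's rho with exon number and with span were 0.24 and 0.21 in Cal51 G579S, -0.13 and -0.03 in DLD1, -0.08 and -0.16 in MDA-MB-231 and -0.06 and -0.06 in A375. The Cal51 value rests on DMSO libraries of which 1 stood apart from the other. The values of MDA-MB-231 wild-type rest on OTS964 libraries that differed by a mean chi-square of 85.93 per gene. They were not computed without either library. A shift of all genes, such as that of -0.55 under library totals, moves these medians together and leaves their order.

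**Figure D3:**
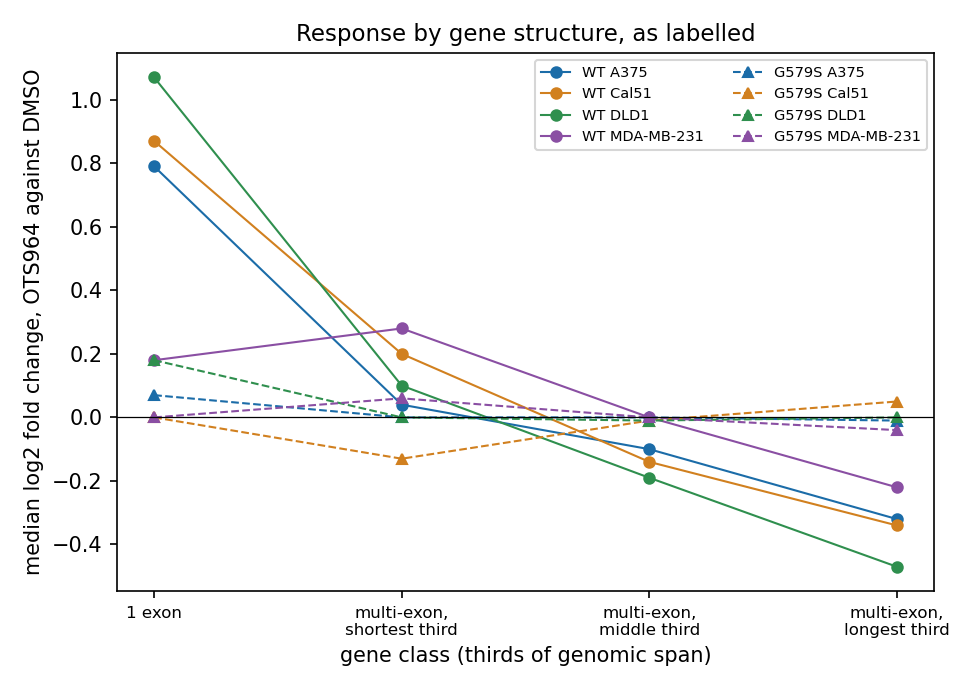
The median log2 fold change of OTS964 against DMSO is plotted for genes with 1 exon and for the 3 groups of genes with several exons by genomic span, with a line for each labelled cell line and genotype. In cells labelled wild-type the longest genes had the lowest medians, between -0.22 and -0.47 by line; the level of every point, but not the order, moves with the scaling.

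The relative use of a gene's transcripts changed in 390 of 6402 genes in cells labelled wild-type, by edgeR's test of transcript usage with the Simes method. For ASB6, an adaptor of ubiquitin ligases, 1 transcript made up 68.7% of the gene's counts with OTS964 and 0% under DMSO (adjusted p = 0.0015). Transcripts at 0% under DMSO reached 36.9% for the growth factor adaptor FRS2 (adjusted p = 2.7e-05), 36.7% for the lipogenesis regulator MID1IP1 (adjusted p = 1.7e-05), 34.1% for the chromatin reader ZMYND8, 21.1% for the apoptosis inhibitor BIRC6 and 16.4% for SMAD3, which carries TGF-beta signals. Transcripts that fell to 0% made up 29.4% under DMSO for the kinase ABL2, 24.5% for the chromatin factor JADE1 and 0.2% for the glycolytic enzyme PKM. In G579S cells 7 of 6618 genes passed, and 329 had an unadjusted p under 0.05. Transcripts of TBRG4, TAF1C, BPTF and HNRNPR went from 0%, 1.7%, 1% and 0% of their gene's counts to 13.3%, 25.8%, 10.3% and 2.2%. A second transcript of BPTF went from 17.8% to 0%, and transcripts of SYNCRIP and CD63 from 8.5% and 1.7% to 1.2% and 0%. All of these percentages come from counts summed over the 8 libraries of a treatment, so single libraries can weigh heavily in them. They cover matched transcripts only, and reads assigned to an unmatched transcript of the gene would change them. The count in wild-type cells was 186 without A375, 172 without Cal51 and 190 without the libraries labelled DLD1, and the count in G579S cells was 2 without DLD1 and 4 without MDA-MB-231.

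Responses of the lines labelled wild-type differed in part, tested as the response of a line minus the mean response of the other lines. MDA-MB-231 differed at 3489 genes (2301 higher), Cal51 at 1994 (937 higher), the libraries labelled DLD1 at 693 (238 higher) and A375 at 669 (320 higher). The libraries labelled DLD1 wild-type resembled A375, so for A375 and for DLD1 the mean of the other lines held a similar response. For Cal51 and MDA-MB-231 that mean held both. These contrasts were not refitted without the libraries labelled DLD1 wild-type. With library totals 448 of 2093 genes were higher in Cal51 and 437 of 634 in A375. The 2 wild-type OTS964 libraries of MDA-MB-231 stood apart, with correlations of 0.906 and 0.94 with its wild-type DMSO libraries. No list was tested without either of them. Relative to the other lines, E2F and replication genes were higher in MDA-MB-231, with 20 higher and 1 lower of 51 (24 and 1 adjusted over the list alone). The camera adjusted p was 1e-04, and adjusted p = 0.29 with an estimated correlation. There 18 of 48 KRAB zinc finger genes and 14 of 35 immediate early genes were lower than in the other lines (adjusted p = 1.4e-05 and 0.00021). Both had an adjusted p = 0.29 with an estimated correlation. Cholesterol genes there counted 12 higher and 1 lower (adjusted p = 0.0051, and adjusted p = 0.1 with an estimated correlation). ATF4 genes counted 3 higher and 8 lower (adjusted p = 0.0069, and adjusted p = 0.09 with an estimated correlation), and SIRT7, a nuclear deacetylase, responded by 9.06 more (adjusted p = 1.4e-07), although it went from 25.7 to 16.8 CPM in MDA-MB-231 itself. In Cal51, 15 of 44 mitosis genes and 17 of 51 E2F genes were lower than in the other lines (adjusted p = 1.9e-08 and 1.1e-05, and adjusted p = 0.6 and 0.25 with an estimated correlation). CIITA, the regulator of MHC class II genes, was 6.21 higher there (adjusted p = 2.2e-06). In the libraries labelled DLD1, 10 of 35 immediate early genes were higher and 0 lower (19 and 3 adjusted over the list alone). The camera adjusted p was 1.6e-07, and adjusted p = 0.44 with an estimated correlation. In A375, 7 of 48 KRAB genes were higher (14 adjusted over the list alone; adjusted p = 5.9e-09, and adjusted p = 0.35 with an estimated correlation). Counts moved by more than 1.5 times when single libraries were left out. That of A375 lay between 229 and 259 without either of its DMSO libraries or its second OTS964 library. It was 1499 without the second OTS964 library labelled DLD1 and 2021 without the second of MDA-MB-231, which also took the DLD1 count to 1429. The DLD1 count was 392 without its first DMSO library and 1427 without its second OTS964 library, and the Cal51 count lay between 1146 and 1301 without any 1 of its 4 libraries.

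Far fewer genes passed in G579S cells, and this comparison asks which changes appear in cells labelled as resistant. Across lines CREBZF again led the genes that rose, from 13.6 ± 4.28 to 42.8 ± 25.3 CPM (SD, n = 8), by 1.49 ± 0.20 (SE; adjusted p = 0.0037). CCNL1 followed at 1.31 ± 0.27 (adjusted p = 0.025), with TAF1D, a factor for ribosomal RNA transcription, at 1.07 (adjusted p = 0.017). The splicing factor RBM39 stood at 1.02 (adjusted p = 0.026) and the zinc finger gene MYNN at 0.97. FANCL, the ubiquitin ligase of the Fanconi pathway, fell by 1.21 ± 0.15 (adjusted p = 0.0024), and SLC35F5, CABYR, ELMOD3 and GAPVD1 fell, with log2 changes of -1.34, -1.31, -1.29 and -1.24. In all, 348 of 14314 genes passed, 181 higher and 167 lower, and 18 of them changed at least 2-fold, while 3145 had an unadjusted p under 0.05. The count was 7 without A375, 28 without DLD1 and 1792 without Cal51, and 807, of which 98 were higher, with library totals. The mean of the contrasts within lines gave 2084 genes and DESeq2's Wald test 1784. MYC rose by 0.40 (adjusted p = 0.026) and SRSF1 by 0.35 (adjusted p = 0.0025), while CDK11A, CDK11B, CCNL2, SF3B1, MDM2 and CDKN1A stood at 0.05, 0.20, 0.37, 0.27, 0.30 and -0.25 with adjusted p of 0.83, 0.20, 0.26, 0.095, 0.11 and 0.23. CCNL1, CREBZF and MYC did not pass without A375 or without DLD1.

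Among the fixed lists, 9 of 45 spliceosome genes rose in G579S cells and 0 fell (18 and 0 adjusted over the list alone). They included SF1 at 0.49, SF3B3 at 0.34, U2AF2 at 0.32 and PRPF3 at 0.82 (camera adjusted p = 9.2e-12, and adjusted p = 0.26 with an estimated correlation). Immediate early genes counted 5 higher of 35 (13 adjusted over the list alone), with CCN1, DUSP6 and IER5 at 0.71, 0.39 and 0.26 (adjusted p = 1.5e-05, and adjusted p = 0.26 with an estimated correlation). ATF4 genes counted 2 higher of 28 (8 adjusted over the list alone), the stress phosphatase subunit PPP1R15A at 0.38 and the amino acid transporter SLC3A2 at 0.35 (adjusted p = 9.5e-06, and adjusted p = 0.39 with an estimated correlation). SR proteins and splicing kinases counted 2 higher and 1 lower of 30 (12 and 2 adjusted over the list alone), with SRSF2 at 0.63 and SRSF5 falling by 1.07 (adjusted p = 0.003, and adjusted p = 0.39 with an estimated correlation). None of the 76 ribosomal, 49 oxidative phosphorylation or 48 KRAB genes passed singly by edgeR. Camera placed the lists above other genes, with medians of 0.20, 0.10 and 0.20 (adjusted p = 2.5e-10, 0.0093 and 0.011, and adjusted p = 0.5, 0.75 and 0.39 with an estimated correlation). The median of oxidative phosphorylation became -0.02 with library totals. In the list of homologous recombination 1 gene, FANCL, fell (camera adjusted p = 0.0011, and adjusted p = 0.39 with an estimated correlation).

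The 4 lines labelled G579S differed in how much they responded. In DLD1 G579S 3369 genes passed (1551 higher), against 94 in A375 (55 higher), 56 in Cal51 (20 higher) and 44 in MDA-MB-231 (32 higher), with 4827, 1292, 1935 and 1752 genes at an unadjusted p under 0.05. With library totals 527 of 3358 genes were higher in DLD1 G579S, 35 of 150 in A375, 14 of 67 in Cal51 and 8 of 33 in MDA-MB-231. In DLD1 G579S CCNL1 rose from 12.1 to 77.2 CPM, by 2.67 (adjusted p = 3.7e-05), SF3B1 by 0.71, MDM2 by 0.73, CCNL2 by 0.91, MYC by 0.52 and SRSF1 by 0.39, and CDKN1A fell by 0.96 (adjusted p = 0.00012). Spliceosome genes counted 26 higher and 1 lower (29 and 1 adjusted over the list alone; camera adjusted p = 9.4e-11, and adjusted p = 0.00061 with an estimated correlation). ATF4 genes counted 11 and 0 of 28 (adjusted p = 2.6e-06, and adjusted p = 0.00061 with an estimated correlation). For ribosomal genes the counts were 54 and 0 (adjusted p = 8.8e-17, and adjusted p = 0.44 with an estimated correlation), and for homologous recombination 0 and 11 of 34 (adjusted p = 7.1e-05, and adjusted p = 0.16 with an estimated correlation). A test of the DLD1 G579S response against the mean of the other G579S lines, chosen after the data were seen, passed at 1727 genes (668 higher). They included CCNL1 at 1.80 (adjusted p = 0.0071), SF3B1 at 0.58 (adjusted p = 0.0034) and CDKN1A at -0.90 (adjusted p = 0.0015). The same test passed at 694 genes for Cal51, 118 for MDA-MB-231 and 10 for A375, where 963 had an unadjusted p under 0.05. Among genes named by the fixed rule, HOXA3 was at least 60.1-fold higher and ADCY3 and RGPD6 at least 161-fold and 84.2-fold lower in DLD1 G579S, while AHNAK, at 5.53, rested on the second OTS964 library and stood at -0.52 without it. Without any 1 of its 4 libraries the DLD1 G579S count lay between 1964 and 2164.

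In A375 G579S, CREBZF rose by 1.58 ± 0.31 (SE; adjusted p = 0.02) and the histone deacetylase HDAC9 by 1.57, and TMEM129 fell from 52.6 to 22.0 CPM (adjusted p = 0.00073). REV3L, the catalytic subunit of a translesion polymerase, was at least 206-fold lower, and 3 spliceosome genes rose (camera adjusted p = 3.5e-11, and adjusted p = 0.00092 with an estimated correlation). Reads of genes at 0 in a group, here and in DLD1 G579S, may have been assigned to unmatched transcripts. In Cal51 G579S the amino acid transporter SLC7A5 rose by 1.13 (adjusted p = 0.032) and PKD1 by 0.90, and CYP2W1 and PDE7B were at least 109-fold and 39.5-fold lower. In MDA-MB-231 G579S, IFT140 and SLX9 rose by 3.72 and 2.05 and ARGLU1 and SLF2 fell, with log2 changes of -0.99 and -0.87. Immediate early genes counted 3 higher of 35 (8 adjusted over the list alone; camera adjusted p = 6.3e-06, and adjusted p = 0.22 with an estimated correlation). These counts moved with the fit and with single libraries. In a fit of the 8 libraries of a line alone, 266 genes passed in A375, 0 in Cal51 and 0 in MDA-MB-231. Leaving out any 1 of the 4 libraries gave between 15 and 34 genes in A375 and between 7 and 16 in MDA-MB-231. Cal51 gave 2211 genes without the first Cal51 G579S DMSO library and between 5 and 11 without any other. The 2 Cal51 G579S DMSO libraries differed from each other by a mean chi-square of 86.86 per gene, against a range from 5.68 to 47.84 in all groups but that of MDA-MB-231 wild-type OTS964, at 85.93. The second of them had a correlation of 0.938 with Cal51 wild-type DMSO, against 0.966 for the first and 0.963 and 0.962 for the Cal51 G579S OTS964 libraries. The 2211 genes therefore rest on the library that stood apart.

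The difference between the responses of cells labelled wild-type and G579S asks which changes depend on sensitivity to CDK11 inhibition. Across lines it passed at 7173 genes, 3482 higher and 3691 lower in wild-type, and at 6834 without the 4 libraries labelled DLD1 wild-type. MYC responded by 2.68 more in wild-type (adjusted p = 2.2e-09), CCN1 by 3.39, DUSP5 by 1.84 and CDKN1A by 1.07, whereas MDM2 stood at -1.43. CDK11A stood at -0.41 (adjusted p = 0.0058), CDK11B at -0.37 (adjusted p = 0.018) and SRSF1 at -0.18 (adjusted p = 0.039). CCNL1 stood at 1.17 (adjusted p = 0.055) and CCNL2 at -0.45 (adjusted p = 0.19), and SF3B1 stood at 0.37, or -0.06 with library totals. The largest differences by the fixed rule were those of CLUH, with no counts in wild-type DMSO libraries and at least 43-fold higher with OTS964, TET3, ST6GALNAC2, C10orf55 and B3GALT2 among the higher genes, and of PRR14L, ZSCAN29, PHF3, KLHL25 and KCTD21 among the lower. ST6GALNAC2, a sialyltransferase, differed by 4.69 ± 1.03 (SE; adjusted p = 0.00038), KLHL25 by -7.79 ± 0.55 and KCTD21 by -7.78 ± 1.20, and PHF3, a regulator of RNA polymerase II, was at 0 in all 8 wild-type OTS964 libraries, at least 75.4-fold lower than under DMSO. Reads of genes at 0 in a group, such as CLUH and PHF3, may have been assigned to unmatched transcripts. The share of reads on predicted transcripts, most of them unmatched, differed with treatment in wild-type cells.

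All 76 ribosomal protein genes responded higher in wild-type (RPL3 at 0.97; camera adjusted p = 5.6e-25, and adjusted p = 0.3 with an estimated correlation). So did 47 of 49 oxidative phosphorylation genes (ATP5F1B at 0.89; adjusted p = 7.2e-17, and adjusted p = 0.28 with an estimated correlation). Of the mitosis genes 30 of 44 responded lower, CDCA8 by -2.66 (adjusted p = 1.7e-06, and adjusted p = 0.3 with an estimated correlation). Lower responses also held for 11 of 19 transcription kinases and cyclins (12 adjusted over the list alone; adjusted p = 0.0096, and adjusted p = 0.11 with an estimated correlation). Immediate early genes counted 22 higher and 4 lower (adjusted p = 0.00084, and adjusted p = 0.28 with an estimated correlation). Spliceosome genes counted 21 higher and 8 lower, with a median of 0.26 that turned to -0.17 with library totals (adjusted p = 0.035, and adjusted p = 0.43 with an estimated correlation). SR proteins and kinases counted 3 higher and 13 lower, with CLK1 at -2.98 and SRPK2 at -2.06 (adjusted p = 0.035, and adjusted p = 0.3 with an estimated correlation). Single genes of other lists included the polyadenylation factor CPSF7 at -2.43 and the apoptosis genes APAF1 and BAK1 at -1.98 and -3.19. Of the 13 lists past the preset camera test, 0 passed with the estimated correlation, where 3 had an unadjusted p under 0.05. With library totals, the median of all genes moved by -0.43, and 25.8% of called genes were higher in wild-type in place of 48.5%.

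Under DMSO, G579S and wild-type cells were compared to see how the labelled genotypes differed before treatment. Across lines 385 genes passed, 167 higher and 218 lower in G579S, 103 of them at least 2-fold, and the count was 468 without the libraries labelled DLD1 wild-type. These counts do not show that the difference belongs to the genotype rather than to other differences between the cells compared. H2BC12, a histone gene, stood at 89 against 22.6 CPM, higher by 1.97 ± 0.35 (SE; adjusted p = 0.017), with H2BC5 and H2BC21 at 1.61 and 1.38. The histone list counted 3 higher of 38 (9 adjusted over the list alone; camera adjusted p = 3.5e-05, and adjusted p = 0.11 with an estimated correlation). Mitosis genes counted 7 lower of 44, with ESPL1, TPX2 and PLK1 at -0.67, -0.52 and -0.50 (adjusted p = 1.4e-06, and adjusted p = 0.51 with an estimated correlation). The collagenase MMP1 was lower by a log2 change of -3.59 (adjusted p = 0.0072), as were TMPRSS15, SLAMF7, CST4 and SLC14A1, and C6orf15 was higher by 5.78 (adjusted p = 0.004), as were RAB25 and FAM83F. KIT, a receptor kinase of melanocytes, stood at 5.26 in this contrast and at 0.00 without the 4 libraries labelled DLD1 wild-type. Cell-type markers moved in the same contrast, with the colorectal list up (adjusted p = 2.3e-06) and the mesenchymal list down (adjusted p = 0.0042). Neither stood apart without the 4 libraries labelled DLD1 wild-type (adjusted p = 0.17 for both), and nor did the cholesterol list (up, adjusted p = 7.7e-05, then 0.17). The lists of oxidative phosphorylation (up, adjusted p = 0.0042), and of heat shock, the spliceosome core, E2F targets, ATF4, NF-kB and homologous recombination (down, adjusted p = 3.5e-05, 7.7e-05, 0.00015, 0.002, 0.014 and 0.022) passed as well. All 13 lists past the preset camera test were lost with the estimated correlation. DESeq2's Wald test called 1452 genes in place of 385, and the mean of the contrasts within lines 3813. With DESeq2's size factors 216 genes were higher and 181 lower.

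Within single lines the genotypes were tested in the fit of 16 groups, in which the mean of the contrasts gave 3813 genes. The counts by line therefore do not compare with the 385 of the additive fit across lines. In Cal51, G579S cells had CDKN1A at 644 ± 86.1 CPM against 51.8 ± 3.24 CPM (SD, n = 2), higher by 3.64 ± 0.15 (SE; adjusted p = 8.4e-12), and MDM2 at 267 against 106 CPM, higher by 1.34 (adjusted p = 0.00013). Lower in G579S were 36 of 44 mitosis genes (camera adjusted p = 6.4e-22, and adjusted p = 0.036 with an estimated correlation) and 20 of 51 E2F genes (adjusted p = 3.2e-11, and adjusted p = 0.017 with an estimated correlation). Of the interferon-stimulated genes 14 of 28 were higher (adjusted p = 5.9e-06, and adjusted p = 0.0081 with an estimated correlation). MYC stood at -0.80 in Cal51, and 2436 genes passed there, 1471 of them higher. That count was 1392 and 1173 without the first and the second wild-type DMSO library, 1487 without the second G579S DMSO library, which stood apart, and 3418 without the first. In A375 1397 genes passed, and between 748 and 778 without any 1 of the 4 libraries. There 10 of 24 NF-kB genes were lower in G579S (adjusted p = 3e-06, and adjusted p = 0.055 with an estimated correlation), as were 7 of 23 mesenchymal markers (adjusted p = 0.00073, and adjusted p = 0.015 with an estimated correlation). Of 14 melanocyte markers 5 were higher (adjusted p = 0.00063, and adjusted p = 0.056 with an estimated correlation). In MDA-MB-231 1043 genes passed, 392 higher, among them CDK11B, and between 410 and 503 without any 1 of the 4 libraries. N4BP1 was at least 206-fold lower in G579S, and 5 of 24 NF-kB genes were lower (adjusted p = 7.2e-05, and adjusted p = 0.15 with an estimated correlation). Reads of a gene at 0 in a group may have been assigned to an unmatched transcript. Within the MDA-MB-231 G579S DMSO pair, 73 genes were at 0 in 1 library and at 5 CPM or more in the other. Between the libraries labelled DLD1 G579S and DLD1 wild-type 7037 genes differed. Colorectal markers were higher in G579S at 18 of 19 genes (adjusted p = 6.8e-14, and adjusted p = 0.0037 with an estimated correlation). Melanocyte markers were lower at 11 of 14 genes (adjusted p = 3.7e-07, and adjusted p = 0.0043 with an estimated correlation) and mesenchymal markers at 16 of 23 (adjusted p = 1.7e-07, and adjusted p = 0.00027 with an estimated correlation). SYDE1 and the basement membrane gene NID1 were at least 1150-fold and 897-fold lower in DLD1 G579S.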

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

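The tests of a wrong label, a label swap, a change of identity by the edit, the source of the falls in DLD1 G579S, the sum of the CDK11 paralogs, the relabelled samples and the exchanged groups were chosen only after the results they concern had been seen; the others were fixed before.

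The wild-type and G579S responses to OTS964 differed, by a test of the difference itself, at 4859 genes in A375, 6553 in Cal51, 5255 in the libraries labelled DLD1, 3797 in MDA-MB-231 and 7173 across lines. The wild-type response of a line differed from the mean of the other lines at 669 genes in A375, 1994 in Cal51, 693 in the libraries labelled DLD1 and 3489 in MDA-MB-231. The libraries labelled DLD1 wild-type resembled A375, so for A375 and for DLD1 that mean held a similar response. Of 100 relabellings of treatments within lines, 1 draw, the real labels, gave as many genes for the wild-type response (8424, highest other 5619), and likewise for the G579S response (348, highest other 1). The same count of 1 held for the difference of responses (7173, highest other 5335). For the genotypes under DMSO it was also 1 (385, highest other 335). Most of these draws part the 2 libraries of a group, which puts differences between groups into the spread and keeps their counts low. They therefore do not exclude chance, and they do not test whether differences of separately grown groups agreed over the lines by chance. Exchanging whole groups within lines gives 8 splits, too few for a share under 0.05. In these the genotypes under DMSO reached 385 genes with the real labels and 412 as the highest other, so that 2 of 8 splits gave as many. The G579S response reached 348 against 277 (1 of 8) and the wild-type response 8424 against 1516 (1 of 8). Transcript usage in wild-type cells gave 390 genes against at most 66 in the others (1 of 100). In G579S cells 7 genes passed and 2 of 100 draws, the real labels included, gave as many, with a highest other of 7. Among the 40 draws made at first 2 did so as well, a share of 0.05 that does not exclude chance. The number of draws was raised only after that was seen, so the 100 draws cannot exclude chance for this count either. Whole groups were not exchanged for transcript usage.

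The first pattern is that the libraries labelled DLD1 wild-type differed from DLD1 G579S throughout. Against A375 wild-type the DMSO libraries differed at 741 genes, 10.5% of the 7037 at which they differed from DLD1 G579S and fewer than the 1397 that separate A375 G579S from A375 wild-type, which is consistent with A375 cells under a DLD1 label. An exchange of labels with A375 is argued against, since 4 of the 4 libraries labelled A375 wild-type lay nearer to A375 G579S than to DLD1 G579S, and so is a change of identity through the G579S edit, since in each library labelled DLD1 wild-type the melanocyte list exceeded the colorectal list, by at least 1.52 in log2 CPM. A small share of DLD1 RNA may be present too, because 67 genes high in DLD1 G579S and near 0 in A375 stood at a median of 2.69% of their DLD1 G579S level, with quartiles of 1.94% and 3.36%. Where and when the material was exchanged or mixed stays open, and beyond the edit no biological explanation was tested.

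The second pattern is that DLD1 G579S changed at 3369 genes with OTS964 where the other G579S lines changed at 94 or fewer. Depth is argued against, since 3328 genes passed after the 4 libraries were thinned to 14621045 counts, and so is A375 RNA in the treated libraries, since 110 genes of A375 had a median log2 change of -0.74 and a median level of 0.144 CPM. Sensitive cells among the G579S cells may contribute, as 88.5% of the 200 genes that rose most in the wild-type contrasts of the other lines were also positive in DLD1 G579S, 97 of them past the threshold, but 85.5% were so in MDA-MB-231 G579S as well, with 77% in A375 and 55% in Cal51. Of the genes over 2-fold lower in DLD1 G579S, 39.6% (371 of 936) were over 2-fold lower by the median of the wild-type contrasts of the other lines, against 25.2% of all genes. That median cannot show falls particular to sensitive DLD1 cells, since the libraries labelled DLD1 wild-type resembled A375. Whether sensitive cells were the source of these falls is therefore not decided. A response of this clone or line that does not depend on CDK11 inhibition remains open and untested.

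The third pattern is the level of CDK11B in MDA-MB-231 G579S. Reads moved between the paralogs are argued against, since the sum of CDK11A and CDK11B was 7.21-fold higher in G579S than in wild-type cells under DMSO. More copies of the surrounding region are argued against as well, since 19 tested neighbours had a median log2 difference of 0.03, with 0 higher and 2 lower. Extra copies of CDK11B alone, an introduced transgene and a stronger promoter stay open and were not tested, since the design names only the genotype.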

How the results depend on the processing

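Fits without the libraries labelled DLD1 wild-type or without the first MDA-MB-231 wild-type OTS964 library, and single-exon genes without histones, were chosen after the data were seen; all other alternatives were planned. Over 349 pairs of a named gene and a contrast, 4658 values kept their direction and their side of the threshold, 46 became stronger, 16 reversed and the rest became weaker. Of the lists 465 values kept theirs, 62 became weaker, 24 stronger and 1 reversed. Apart from the minimum fold change, the count across lines lay between 7467 and 9017 for the wild-type response and between 6216 and 7755 for the difference of responses. Unless stated, the cause of a change was not tested.

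With a minimum fold change of 2, fewer genes pass by construction: 4650 for wild-type across lines, 3477 in A375, 4459 in DLD1 and 3677 in MDA-MB-231; for G579S 18 across lines, 17, 14, 1138 and 14 in A375, Cal51, DLD1 and MDA-MB-231; for the difference 3780 across lines, 2919 in A375, 3354 in DLD1 and 1808 in MDA-MB-231; for the genotypes under DMSO 103 across lines and 696, 947, 4462 and 370 by line; and for a line minus the others 315, 849, 360 and 1976. DESeq2's Wald test called 1452 genes between the genotypes under DMSO across lines, 2122 in A375 and 1889 in MDA-MB-231, 1784 for G579S across lines with 442, 565 and 426 in A375, Cal51 and MDA-MB-231, and 1397 and 1245 for A375 and DLD1 minus the others. DESeq2 size factors gave 29 for G579S in MDA-MB-231 and changed the share higher to 57.9%, 50.5% and 52.6% for A375, DLD1 and MDA-MB-231 minus the others and from 43.4% to 54.4% for the genotypes under DMSO. Library totals gave 807 genes for G579S across lines (12.1% higher in place of 52.0%) and 150 in A375.

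The 8 libraries of a line alone gave, for the genotypes under DMSO, 2492 in A375 and 280 in MDA-MB-231, for G579S 266 in A375, 0 in Cal51 and 0 in MDA-MB-231, where edgeR had 1365 and 1101 genes at an unadjusted p under 0.05, and for the difference 2293 in MDA-MB-231. Averaging the contrasts within lines gave 3813 genes for the genotypes and 2084 for G579S. Replicate numbers were not tied to pairs, as the deviations of same-numbered libraries had correlations between groups neither over 0.1 nor under -0.1 throughout; with the replicate block 0 genes passed edgeR for the genotypes across lines (1724 unadjusted, 1452 by DESeq2 without the block) and 0 for G579S (2400 unadjusted), with 55, 29 and 14 for G579S in A375, Cal51 and MDA-MB-231 and 22 for transcript usage in G579S. G579S across lines gave 7 without A375, 1792 without Cal51 and 28 without DLD1. Transcript usage in wild-type gave 186, 172 and 190 without A375, Cal51 and DLD1 and 998 by the F test; in G579S it gave 63 by the F test, 2 without DLD1 and 4 without MDA-MB-231.

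With the estimated correlation 1 list passed for wild-type (of 9), 0 for G579S (of 8), 0 for the difference (of 13) and 0 for the genotypes (of 13), with 7, 2, 3 and 3 at an unadjusted p under 0.05; fry gave 20, 5 and 5 for wild-type, G579S and the genotypes. Library totals reversed SRSF1 in wild-type (-0.34, -0.69, -0.37, -0.11 and -0.38 in A375, Cal51, DLD1, MDA-MB-231 and across lines), SF3B1 in MDA-MB-231 (-0.11) and in the difference (-0.06), SYMPK (0.00) and ERBB2 (-0.07). Length-scaled TPM put CCNL2 at 0.69. Without the libraries labelled DLD1 wild-type KIT stood at 0.00 and the melanocyte list, now of the opposite sign, had an adjusted p of 0.006. Single libraries decided the genes that follow, given as the range over libraries left out: RBM12B for A375 minus the others (-0.03 to 8.82, lowest without the first A375 wild-type OTS964 library), AHNAK for G579S in DLD1 (-0.52 to 6.53, lowest without the second OTS964 library), and ZNF263 and MIER2 for DLD1 minus the others (-0.66 to 10.49 and -4.71 to 6.95, lowest without the first DLD1 wild-type OTS964 library).

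Leaving out 1 library at a time, the lone library being assumed to vary like the other groups, gave for A375, Cal51, DLD1 and MDA-MB-231 in turn: wild-type 5418 to 5473, 6572 to 6673, 6228 to 6835 and 5595 to 7076; G579S 15 to 34, 5 to 2211, 1964 to 2164 and 7 to 16; the difference 3857 to 4621, 5848 to 6660, 4291 to 5520 and 2651 to 4982; the genotypes 748 to 778, 1173 to 3418, 5693 to 5870 and 410 to 503; and a line minus the others 229 to 2021, 1146 to 2667, 392 to 1429 and 2497 to 4831. Thinning the DLD1 G579S libraries to equal total counts gave 3328 calls in place of 3369. Retained-intron tests were not run.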

Other observations

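No test of an explanation was run on the values given here, and the comparison of gene sets across genotypes was chosen after the responses were seen.

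Under DMSO, further groups differed between Cal51 G579S and Cal51 wild-type beyond mitosis. The second Cal51 G579S DMSO library stood apart from the first, the count of genes being 1487 without the second and 3418 without the first, and the lists were not tested without either. Of 49 oxidative phosphorylation genes 24 were higher in G579S and 0 lower (38 and 0 adjusted over the list alone; camera adjusted p = 1.1e-09, and adjusted p = 0.24 with an estimated correlation), and of 38 replication-dependent histone genes 8 were higher (adjusted p = 0.00057, and adjusted p = 0.015 with an estimated correlation). Of 34 genes of homologous recombination 12 were lower (adjusted p = 2.5e-06, and adjusted p = 0.031 with an estimated correlation), as were 11 of 45 spliceosome genes (adjusted p = 3.3e-05, and adjusted p = 0.015 with an estimated correlation), while 5 of 19 colorectal epithelial markers were higher (adjusted p = 1.2e-05, and adjusted p = 0.042 with an estimated correlation). SPATA18, a gene of mitochondrial quality control, was at least 102-fold higher in G579S, and the collagen gene COL3A1, NIBAN1 and the kinase gene RPS6KA2 were lower by log2 changes of -5.92, -4.73 and -4.42. OTUD4, a deubiquitinase, had no counts in the wild-type DMSO libraries of Cal51 and MDA-MB-231 and was at least 200-fold and 178-fold higher in their G579S libraries. Its reads in the wild-type libraries may have been assigned to an unmatched transcript. In DLD1 G579S against the libraries labelled DLD1 wild-type, 18 of 24 cholesterol synthesis genes were higher and 2 lower (adjusted p = 4e-05, and adjusted p = 0.0043 with an estimated correlation), 24 of 45 spliceosome genes were lower (adjusted p = 0.0046, and adjusted p = 0.071 with an estimated correlation) and 14 of 21 heat shock genes were lower (adjusted p = 0.013, and adjusted p = 0.071 with an estimated correlation).

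The responses of wild-type and G579S cells overlapped. Across lines 266 genes passed in both genotypes, and 215 of them moved the same way, 102 higher where independent lists of these sizes would share 49 and 113 lower where they would share 53. The genotypes have separate DMSO libraries, so no control is shared. The overlaps within lines rest on G579S counts that moved with single libraries. That of MDA-MB-231 went from 44 to between 7 and 16, and to 0 in a fit of the line alone, and that of A375 from 94 to between 15 and 34. Within lines, 37 of the 38 genes past the threshold in both genotypes of MDA-MB-231 moved the same way, with a Spearman's rho of 0.46 across all genes, and 43 of 64 in A375, with a rho of 0.06. In Cal51, where the G579S count went from 56 to between 5 and 2211 with single libraries left out and 1 DMSO library stood apart, 16 of 39 did, with a rho of -0.15, and in the libraries labelled DLD1 1766 of 2418, with a rho of 0.22. The libraries labelled DLD1 wild-type resembled A375, so by the markers the DLD1 value does not compare genotypes of the same line. A375 wild-type against DLD1 G579S gave 1756 of 2320, with a rho of 0.25. Genes are not independent replicates, and the difference between these values was not tested.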
